A study of Mus musculus with 16 samples.

How the data were processed

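Male C57BL/6 mice, 8 weeks old and either wild type (WT) or lacking CD200R (KO), had been inoculated with NB9464D neuroblastoma cells, and on day 28 the tumors had been disrupted and digested with collagenase (1 mg/mL), per the labels. Either all cells or CD45+ sorted leukocytes had been captured with 10x Genomics 3' chemistry. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.0.5 and the genome build mm10, without the role of each. The deposited values are natural log values, ln(1 + 10000 × UMIs of the gene / total UMIs of the cell), although the authors named the matrix as counts. Total UMI counts per cell, numbers of genes and cell type names were deposited by the authors beside them. How the authors filtered cells is not stated: the smallest cell has 500 UMIs and 200 genes, and the largest total is 126881 UMIs.

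Counts were recovered by inverting the formula with each cell's deposited total. All 60957742 nonzero values were whole within 0.01 UMI, and in all 20376 cells the recovered sum over 19715 genes equalled the deposited total. The labels name CD200R-/- mice among the sample characteristics and CD200-/- mice in the growth protocol. The labels give 16 samples in 4 groups of 4, but cells carry only 1 library name per group, and the samples could not be told apart. Each group was therefore 1 library (WT sorted, KO sorted, WT tumor, KO tumor), and the rule set for that case was followed: no test, no p-value and no spread between replicates, and only values with counting intervals. With 1 library per group the genotype cannot be separated from differences between animals, grafts or preparations of the same group.

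The 19 cell type names of the authors were pooled into 14 classes, M1 and M2 macrophages forming the monocytes and macrophages. Each name was checked against a fixed list of markers. Cells named neuroblastoma and fibroblasts had 0 of their own markers among their leading genes, and 0 of another class. The check thus did not bear out these 2 names, which are kept as the authors gave them. The authors' hematopoietic stem cells were led by B cell markers, with the mast cell genes Cma1 and Mcpt4 also among their leading genes. Their cancer stem cells were led by erythroid genes. Neither class is therefore reported by name, and endothelial cells, plasmacytoid dendritic cells and stem cells had too few cells. The classes named hematopoietic and cancer stem cells are also left out of the leukocyte classes, in every share of leukocytes. Classes were compared within a preparation where each library had at least 50 cells. No cells were removed as doublets in the values reported. The doublet alternative removed cells with UMIs of at least 3 markers in each of 2 lineages, 22.5% of WT sorted, 11.1% of KO sorted, 20.5% of WT tumor and 9.12% of KO tumor cells, which also takes out deep single cells.

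UMIs were summed per gene, class and library and scaled to all UMIs of the class and library (CPM). Intervals are at 95%: exact Poisson for CPM, Clopper-Pearson for shares and conditional binomial for ratios. Where a genotype had 0 UMIs the ratio was taken against a floor of 3 counts and is given as a bound. The log2 ratio KO over WT of the median gene by total UMIs was also 0.45 in sorted B cells, 0.57 in T cells, 0.36 in NK cells, 0.28 in dendritic cells, 0.40 in neutrophils, 0.43 in regulatory T cells, 0.38 in fibroblasts and 0.26 in neuroblastoma cells, so ratios of genes and lists are relative to the median gene. Counts of genes used those with at least 50 UMIs over both libraries of each preparation and a 2-fold difference in both preparations. Lists used members with at least 20 UMIs and 1.5-fold, and each median was placed among 10000 random lists drawn from 20 bins of expression (seed 1). The intervals of list medians are binomial order statistics over the genes.

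The 25 lists were written before the data were examined, as were the classes of comparison, thresholds and alternatives, except where said. They cover chemokines, chemokine receptors, the CD200 receptor family, alternative activation, interferon gamma targets, type I interferon response, MHC class I and II, NF-kB feedback, inflammatory cytokines, hypoxia and glycolysis, lipid-associated genes, extracellular matrix remodelling, complement, cell cycle, dissociation stress, checkpoint ligands, erythrocyte and platelet RNA, fibroblast RNA, cytotoxic, exhaustion, naive and memory T cell, regulatory T cell, T helper cytokine and neuroblastoma identity genes. Named genes followed a rule: Cd200r1 and Cd200, every chemokine with at least 20 UMIs in sorted monocytes and macrophages, the leading members of each list and the largest against it, and the 10 highest and 10 lowest genes of monocytes and macrophages (5 and 5 in other classes). For these, at least 50 CPM in 1 genotype, 100 UMIs in the sorted and 20 in the tumor libraries and 1.5-fold in the same direction in both were required. The ranking used the sorted libraries, or the tumor libraries for neuroblastoma cells and fibroblasts. Left out of that ranking were mitochondrial genes (4.16% of UMIs of WT and 5.68% of KO sorted monocytes and macrophages), ribosomal protein genes (14.9% and 13.0%), hemoglobin genes (0.0389% and 4.56e-05%) and variable segments of antigen receptors. Further genes of neutrophils, the regulatory T cell class and dendritic cells (Cd200r3, Gata2, Ms4a2, Il4, Foxp3, Gata3, Rora, Areg, Ccl17, Ccl22) were chosen after their values were seen. Some genes that the rule names are not reported here. Coordinates are from GENCODE release M21.

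The code was tested on simulated counts drawn from the means and library sizes of monocytes and macrophages. With 7431 genes, a 2-fold difference in both preparations was called for 19.1% of the genes changed 2-fold, 100% of those changed 4-fold and 100% of those changed 8-fold, none in the wrong direction, and for 0 of 7245 unchanged genes. The intervals held the true ratio for 95.7% of genes in the sorted and 95.6% in the tumor libraries. Of 200 unchanged lists, 12 lay outside the middle 95%. The simulated counts were Poisson draws without spread between animals, cells or preparations. These rates therefore cover counting error alone and are not error rates of the calls in the data.

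Alternatives were a stricter cell filter (at least 1000 UMIs and 500 genes, at most 10% mitochondrial UMIs), doublet removal, classes rebuilt from markers, leukocytes alone as denominator, TMM and median-of-ratios scaling, no filter or at least 100 UMIs, equal weight per cell, thinning of cells to 2000 UMIs (which leaves out shallower cells, 803 of the WT sorted, 1179 of the KO sorted, 318 of the WT tumor and 951 of the KO tumor library), 1.5-fold instead of 2-fold, M1 and M2 macrophages alone, mean instead of median of lists, and at least 200 UMIs for correlations. Alternatives chosen after seeing the data were counts relative to the median gene, genes and lists by total UMIs, and removal of cells with basophil markers from neutrophils. The versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.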

Results

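Single-cell RNA sequencing had been carried out on subcutaneous tumors grown from NB9464D cells, a mouse neuroblastoma line, in male C57BL/6 mice that were wild type (WT) or lacked CD200R (KO). CD200R, encoded by Cd200r1, is an inhibitory receptor of myeloid cells, and its ligand CD200 is a membrane glycoprotein found on lymphocytes, endothelium and some tumor cells. Tumors had been collected on day 28, and either CD45+ leukocytes sorted from them or all tumor cells had been loaded. The series title names the question, which is how CD200R signaling affects chemokine production by myeloid cells. The labels list 16 samples, 4 for each combination of genotype and preparation, but the cells carry only the name of their combination. Each combination was therefore treated as 1 library, no replicate spread could be measured, and no test was made.

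The WT sorted library held 5219 cells with 62509573 unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule), and the KO sorted library held 4305 cells with 29200338 UMIs. The WT and KO tumor libraries held 4955 and 5897 cells with 103277632 and 103877007 UMIs. The median cell had 4665 UMIs in the WT sorted, 3127 in the KO sorted, 19850 in the WT tumor and 16276 in the KO tumor library, with a median of 4.19%, 6.36%, 6.11% and 8.05% mitochondrial UMIs. RNA of ribosomal proteins was 31.0% of UMIs in WT and 19.2% in KO sorted B cells and 25.9% and 18.6% in monocytes and macrophages of the tumor libraries. Such differences in composition bear on every value scaled by total UMIs. Levels are given as CPM, the UMIs of a gene scaled to all UMIs of the class and library. Hemoglobin RNA was at 3025 CPM of the whole WT sorted library and 3.49 CPM of the KO sorted library, against 1002 and 471 CPM of the WT and KO tumor libraries. Intervals are exact 95% intervals, Poisson for levels, Clopper-Pearson for shares and conditional binomial for ratios, and they cover counting error only, not the spread between cells or animals.

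Cd200r1 (chromosome 16, 44765736 to 44794978, plus strand, mm10 coordinates) had 0 UMIs in all KO leukocyte classes. In WT sorted monocytes and macrophages it had 2358 UMIs, a level of 70.5 CPM (67.7 to 73.4), and 52.2% of those cells had at least 1 UMI. In the KO sorted monocytes and macrophages it had 0 UMIs, where 3 counts would be 0.342 CPM. The same class had 65 UMIs and 29.3 CPM (22.6 to 37.3) in the WT tumor library, with a UMI in 19.9% of cells, and 0 UMIs in the KO tumor library, where 3 counts would be 1.45 CPM. WT sorted dendritic cells had 210 UMIs, 52.9 CPM and a UMI in 40.9% of cells, and KO sorted dendritic cells had 0. Over all leukocyte classes the 4 libraries had 2672 (WT sorted), 0 (KO sorted), 76 (WT tumor) and 0 (KO tumor) UMIs. B cells, taken as a class that should lack the gene, had 3 UMIs in the WT sorted library, 0.959 CPM, in 0.309% of cells at a median of 3118 UMIs per cell against 18239 in monocytes and macrophages. Outside leukocytes the KO tumor library held 2 UMIs in fibroblasts and 3 in neuroblastoma cells. With cells thinned to 2000 UMIs, which leaves out shallower cells, the share of cells with a UMI was 11.1% in WT sorted and 9.09% in WT tumor monocytes and macrophages and 4.76% in WT sorted dendritic cells. Where the deleted part of the allele lies is not stated in the labels, so the 3' tags show loss of the transcript and not which exons were removed.

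Cd200 (chromosome 16, 45382135 to 45409053, minus strand) was present in both genotypes, although 1 label names the mice CD200-/-. B cells had 66.2 CPM (57.5 to 75.9) in the WT sorted and 141 CPM (126 to 158) in the KO sorted library, with a UMI in 18.5% and 25.7% of cells and in 11.9% and 20.95% after thinning. Dendritic cells had 49.1 CPM (42.5 to 56.5) and 116 CPM (107 to 125), with a UMI in 22.8% and 32.0% of cells and in 10.6% and 16.2% after thinning. The endothelial cells of the tumor libraries, 13 in each genotype, had 185 CPM in WT and 315 CPM in KO. In monocytes and macrophages Cd200 was low, 4.58 CPM in WT and 9.34 CPM in KO sorted cells. That ratio turned to lower in KO when doublets were removed, when each cell had equal weight, after thinning and within M2 macrophages alone, so no direction is drawn there.

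Among CD45+ sorted cells the KO library held smaller shares of monocytes, macrophages and neutrophils and larger shares of lymphocytes and dendritic cells. Monocytes and macrophages were 30.2% of cells in WT (29.0 to 31.5) and 17.7% in KO (16.5 to 18.9), and neutrophils were 8.28% (7.54 to 9.06) and 2.02% (1.62 to 2.49). The class of regulatory T cells, lymphocytes that restrain other T cells, was 1.80% in WT (1.46 to 2.20) and 9.20% in KO (8.35 to 10.1). Dendritic cells were 3.70% (3.20 to 4.25) and 7.69% (6.91 to 8.53), and NK cells, cytotoxic innate lymphocytes, were 3.56% (3.08 to 4.10) and 6.67% (5.94 to 7.45). T cells were 12.2% and 14.3% and B cells 18.6% and 21.9%. All leukocyte classes together were 78.7% and 80.3%, so a part of the sorted cells was named otherwise in both genotypes. The leading genes of the regulatory T cell class include Ctla4, Il2ra, Areg and Rora, and 2 markers of group 2 innate lymphoid cells are among its top 10. Under classes rebuilt from fixed markers the KO share of regulatory T cells was 6.25 percentage points above WT.

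In the tumor libraries, loaded without a sort, the leukocyte classes were 6.48% of WT cells (5.81 to 7.20) and 20.98% of KO cells (19.9 to 22.04). These leave out the cells named hematopoietic stem cells, which were led by B cell markers and were 3.49% of WT and 3.26% of KO cells. Counting them as leukocytes would move these shares and those among leukocytes alone. Each lymphocyte class was larger in KO: T cells were 0.424% and 3.65% of cells, B cells 1.17% and 5.55%, NK cells 0.242% and 1.34%, and regulatory T cells 0.121% and 1.97%. Monocytes and macrophages were 3.85% of all cells in WT (3.34 to 4.43) and 6.29% in KO (5.68 to 6.94), the opposite direction to the sorted libraries, but of the leukocytes alone they were 59.5% in WT (53.9 to 64.9) and 30.0% in KO (27.4 to 32.6). Neutrophils were 0.343% and 0.356% of all cells, and 5.30% (3.11 to 8.34) and 1.70% (1.05 to 2.58) of the leukocytes. Cells named neuroblastoma were 33.6% in WT (32.3 to 34.9) and 21.8% in KO (20.7 to 22.8), and cells named fibroblasts 49.7% (48.3 to 51.1) and 42.3% (41.0 to 43.5). The border between these classes depended on the naming: with classes rebuilt from markers the KO share of neuroblastoma cells was 16.1 points above WT and that of fibroblasts was -50.5 points from WT. Cells named stem cells were 0.161% in WT and 3.70% in KO, too few in WT to compare their expression.

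**Figure D1:**
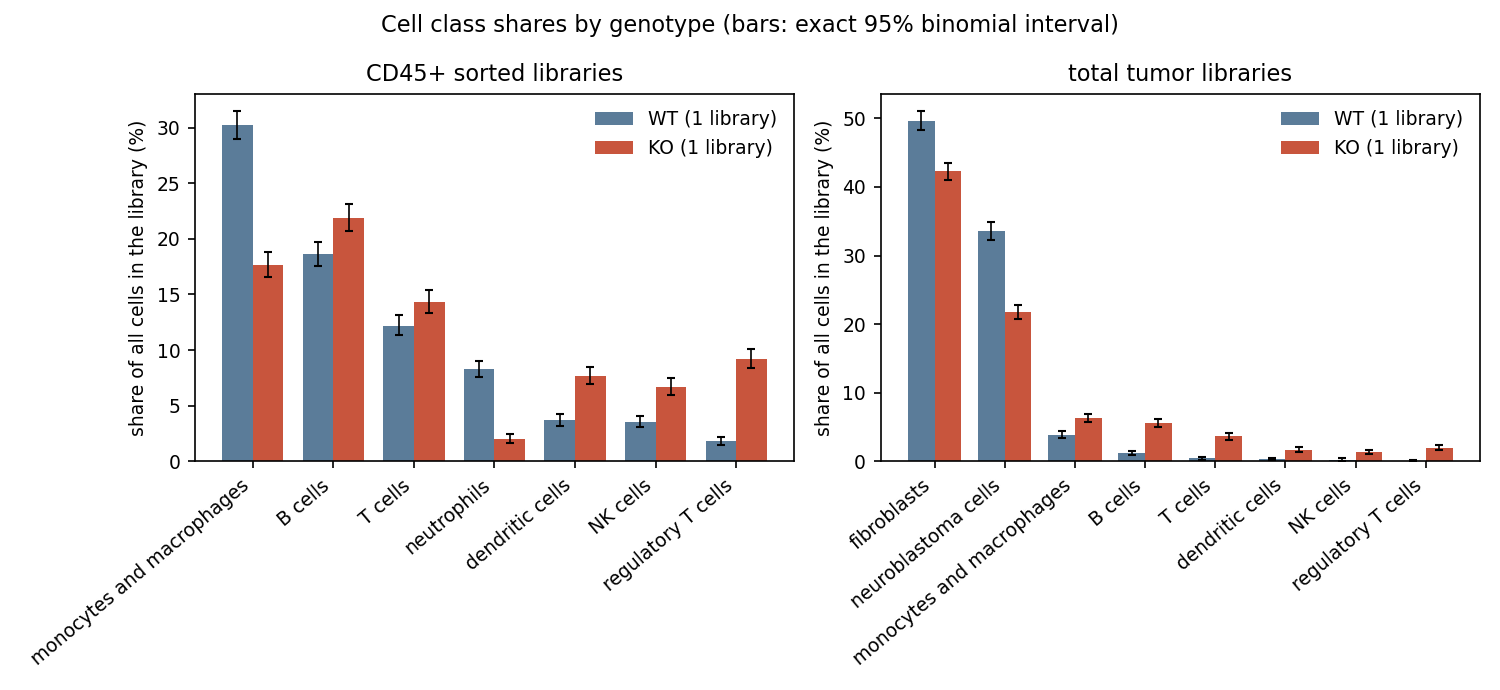
Share of all cells (percent) in each cell class, in the CD45+ sorted libraries (left) and the total tumor libraries (right), with WT and KO side by side, 1 library each, and exact 95% binomial intervals. Monocytes and macrophages are 30.2% of WT and 17.7% of KO sorted cells, and regulatory T cells 1.80% and 9.20%.

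Monocytes and macrophages of KO mice carried far more RNA of Ccl24, Ccl8 and a set of alternative activation genes than those of WT mice, in both preparations, and less RNA of hypoxia and glycolysis genes. Ccl24 encodes eotaxin-2, an attractant of eosinophils, and Ccl8 a ligand of Ccr8 and other receptors. Retnla, Chil3 and Chil4 are induced by interleukin 4 and 13 in mouse macrophages. The class had 1577 WT and 761 KO cells in the sorted and 191 and 371 in the tumor libraries, with 33437902, 8778007, 2219368 and 2064125 UMIs. The KO cells were shallower, with a median of 7955 UMIs against 18239 in the sorted and 2993 against 11579 in the tumor libraries. Scaled by total UMIs, the median gene had a log2 ratio KO over WT of 0.32 in the sorted and 0.31 in the tumor libraries. From here on ratios of genes and lists are therefore relative to the median gene of the class and preparation, and CPM stay scaled by total UMIs. Of the 7455 genes with at least 50 UMIs in each preparation, 418 were at least 2-fold higher and 38 at least 2-fold lower in KO in both preparations by total UMIs (91.7% higher), with 16 in opposite directions. Relative to the median gene the counts were 159 higher and 101 lower (61.2% higher), with 17 in opposite directions.

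Ccl24 (chromosome 5, 135569937 to 135573049, minus strand) had 61.6 CPM (59.0 to 64.3) in WT and 1936 CPM (1907 to 1966) in KO sorted cells, a log2 ratio of 4.65 (4.59 to 4.72), and 19.8 and 720 CPM in the tumor libraries, a ratio of 4.87 (4.44 to 5.34). Ccl8 (chromosome 11, 82115185 to 82116799, plus strand) had 1279 CPM in WT and 6976 CPM in KO sorted cells, a log2 ratio of 2.12 (2.11 to 2.14), and 534 and 4242 CPM in the tumor libraries, a ratio of 2.68 (2.59 to 2.76). Ccl22, a ligand of Ccr4, had 0.598 CPM in WT and 16.3 CPM in KO sorted cells, a ratio of 4.44, and a ratio of at least 3.16 in the tumor libraries, where WT had 0 UMIs. Ccl6 and Ccl9 were also higher, with ratios of 0.65 and 0.58 in the sorted and 0.79 and 0.82 in the tumor libraries, but both were lower in KO within sorted M2 macrophages alone. Ccl2, the main attractant of monocytes through Ccr2, was lower, with ratios of -0.93 and -0.79, although within M1 macrophages of the tumor libraries it was slightly higher. Pf4, a platelet and macrophage chemokine, was lower with ratios of -1.87 and -0.97. Erythrocyte and platelet RNA was also lower in these cells, as given below, and whether Pf4 follows platelet RNA was not tested.

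Of the 37 listed chemokines, 26 had at least 20 UMIs in the sorted libraries and 20 in both preparations. In both preparations 4 were at least 1.5-fold higher (Ccl24, Ccl22, Ccl8 and Ccl6) and 2 at least 1.5-fold lower (Ccl2 and Pf4). The list's median log2 ratio was -0.35 in the sorted libraries, at percentile 19.5 of 10000 random lists of like expression, and 0.80 in the tumor libraries, at percentile 100. Of the attractants of neutrophils, Cxcl2 had a ratio of -1.79 in the sorted libraries, Cxcl3 of -3.97 and Ppbp of -3.11, and Cxcl5 was at least 14.8-fold lower by CPM, with 169 UMIs in WT and 0 in KO. Cxcl1 was higher there (0.45), but lower with equal weight per cell (-0.34), after thinning (-0.21) and within M2 macrophages alone (-0.49). In the tumor libraries Cxcl2 had a ratio of -0.18 (-0.37 to 0.01) and Cxcl3 of 0.16 (-0.43 to 0.77), and Cxcl5 and Ppbp had too few UMIs. RNA of S100a8 and S100a9, abundant in neutrophils and looked up after the values were seen, was at 133 and 156 CPM in WT sorted monocytes and macrophages and at 6.04 and 1.37 CPM in KO ones. Ccl17, with 4 UMIs in WT and 33 in KO, had a ratio of 4.65 in the sorted libraries, Ccl1 of 1.53 and Xcl1 of -0.79, the last turning to 0.05 without doublets. Cxcl9, an interferon-induced attractant of T cells, had a ratio of 0.20 (-0.03 to 0.43) in the sorted libraries and of at least 3.56 in the tumor libraries. For Cxcl16 the ratios were 0.11 and 0.12 (-0.09 to 0.33 in the tumor libraries), for Ccl25 -0.42 and 0.50 and for Ccl27a, which shares sequence with near-identical copies, -0.30 and -0.47, with intervals spanning 0 for the last 2 genes. Cxcl14 had 0.01 in the sorted libraries. For 7 chemokines the direction was opposite in the preparations with both intervals apart from 0: Ccl12 (-0.75 sorted, 0.85 tumor), Ccl3 (-1.14, 0.31), Ccl4 (-0.55, 1.06), Ccl5 (-1.39, 5.36), Ccl7 (-0.34, 0.99), Cxcl10 (-0.36, 1.73) and Cxcl1 (0.45, -0.59). Only Ccl12 and Ccl5 were opposite by at least 1.5-fold in each preparation.

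**Figure D2:**
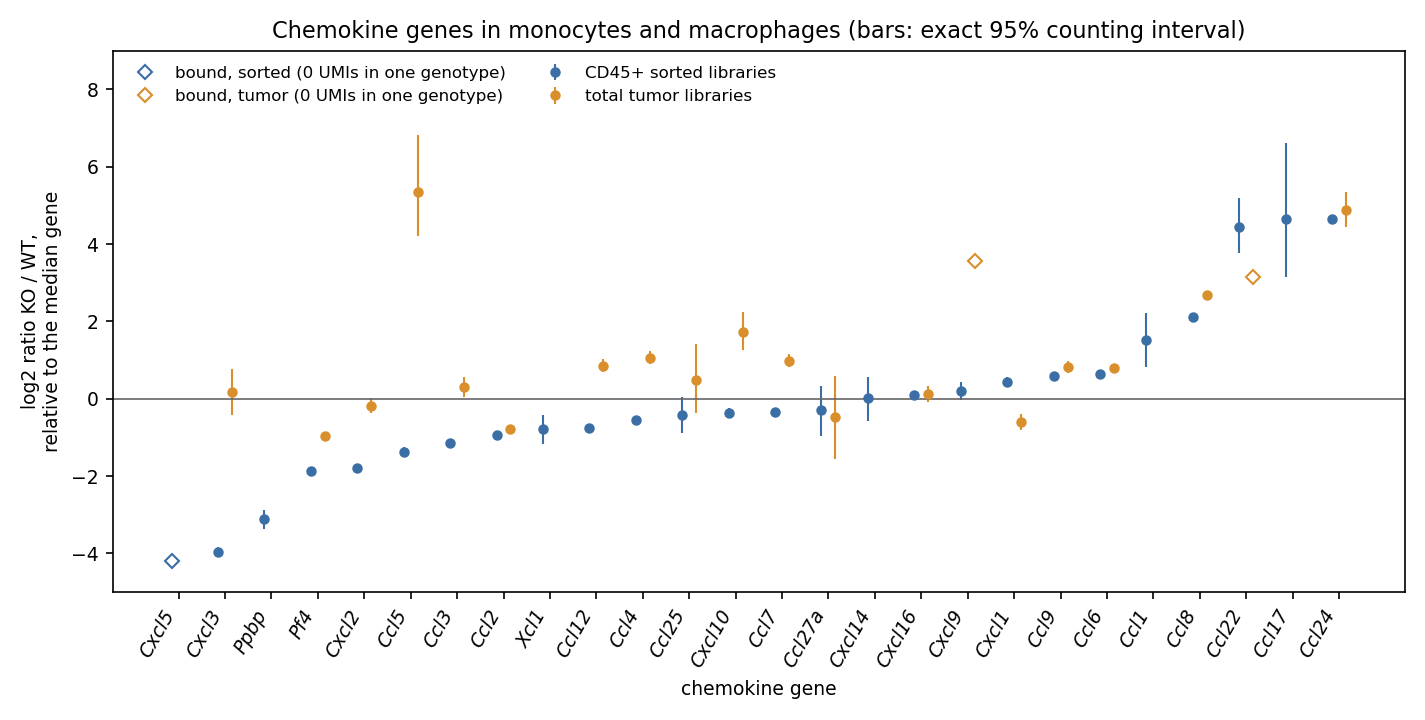
Log2 ratio KO over WT of 26 chemokine genes in monocytes and macrophages, relative to the median gene, in the CD45+ sorted (blue) and total tumor (orange) libraries, 1 library per genotype, with exact 95% counting intervals and open diamonds for bounds. Ccl24 lies at 4.65 and 4.87 and Ccl8 at 2.12 and 2.68, while 7 genes such as Ccl12 lie on opposite sides of 0.

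Among the 10 genes named for the largest ratio in the sorted libraries, besides Ccl24, Retnla, Chil3, Pdcd1lg2 and Slc7a2 mark or serve alternative activation: Retnla had 32.4 CPM in WT and 3675 CPM in KO (ratio 6.50, 6.42 to 6.59; tumor 5.17), Chil3 62.9 and 1222 CPM (3.96, 3.89 to 4.03; tumor 6.70), Slc7a2, an arginine transporter, 4.43 and 277 CPM (5.64; tumor 5.0) and Pdcd1lg2, which encodes PD-L2, a ratio of 4.12 (tumor 3.70). Cd163, a scavenger receptor of resident macrophages, had 9.45 and 270 CPM (4.52; tumor 3.49). The eosinophil-associated ribonucleases Rnase2a (ratio 8.40, tumor at least 6.69) and Ear2 (2.99, tumor 3.00) are close copies of each other, so their split is uncertain. The others were Tmem26 (3.89, tumor 1.67) and the noncoding RNA Gm42031 (4.52, tumor 5.77). This ranking, here and for the other classes, takes genes with at least 50 CPM in 1 genotype that differ by 1.5-fold (by total UMIs) in the same direction in both preparations, so genes named elsewhere can have larger ratios. Under it, besides Cd200r1, the largest ratios in the lower direction were those of Slpi, a protease inhibitor (410 CPM in WT and 28.7 in KO, -4.16), Ifitm1 (-3.08; tumor -1.53), Clec4d (-2.43; tumor -2.00), Smagp (-2.25; tumor -0.97), Arl11 (-2.22; tumor -1.18), Gde1 (-2.03; tumor -0.97), Ftl1, the ferritin light chain (18299 and 5702 CPM, -2.01; tumor -1.03), Ifi27 (-2.00; tumor -0.99) and Ankrd37, a hypoxia-induced gene (-1.98; tumor -1.95). Slpi had -1.92 in the tumor libraries, but 2.66 with the stricter cell filter and 1.22 without doublets, so its direction there is open.

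Alternative activation genes had a median log2 ratio of 0.80 in both preparations, at percentile 100 of the random lists in each, although the interval of the median spanned 0 (-0.52 to 2.90 sorted, -0.23 to 2.38 tumor). Of 20 members measured in both, 11 were at least 1.5-fold higher and 2 at least 1.5-fold lower in both. Chil4 led with at least 6.43 and at least 5.56, and Folr2, a folate receptor of resident macrophages, went against the list with -1.20 and -0.86, though within M2 macrophages of the tumor libraries it had 0.06. Ccl8 is among the leading genes of the class the authors named M1 macrophages, and Ccl24, Chil3 and Slpi of the class named M2 macrophages. Retnla, Mgl2 and Ear2 are among those of the class named myeloid dendritic cells. In the 2 macrophage classes the values were as follows. Ccl24, Ccl8, Chil3, Chil4, Retnla, Cd163, Clec10a, Mgl2 and Socs2 were at least 1.5-fold higher within M1 macrophages alone and within M2 macrophages alone, in both preparations.

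Interferon gamma targets, a set that includes GTPases of cell-autonomous defense, were higher: the median was 1.14 (0.62 to 1.51) in the sorted and 1.41 (0.88 to 1.79) in the tumor libraries, and 10 of 14 members were higher and 0 lower by 1.5-fold in both. The tumor median was 0.72 within M1 and 2.33 within M2 macrophages and 0.85 with equal weight per cell. Iigp1 had 2.48 and 2.45, Gbp2 1.51 and 3.20, Irgm2 1.41 and 1.79 and Ciita, the switch of MHC class II transcription, 1.35 and 2.03. Psmb8, an immunoproteasome subunit, went against them with -1.14 and -0.07 (-0.32 to 0.18). For type I interferon response genes the medians were 0.38 (-0.04 to 0.97) and 1.13 (0.92 to 1.85), with 13 of 29 higher and 0 lower in both, led by Ifi44 (2.27, 1.88), Oas3 (1.51, 2.48), Stat2 (1.47, 1.85) and Oasl2 (1.15, 1.45), and Isg20 against them (-0.48, -0.29). MHC class II genes had medians of 0.53 and 0.85 with 3 of 8 higher, such as H2-Aa (0.92, 1.08) and H2-Ab1 (0.69, 0.95). H2-DMb1 had 0.58 and 0.84 and was lower within M1 macrophages of the tumor libraries. MHC class I genes had 0.24 and 0.77 with 5 of 20 higher, among them Nlrc5 (1.80, 1.22), Tapbp (1.14, 1.13) and Tap1 (0.90, 1.26), and H2-M3 against them (-0.32, -0.12). In the tumor libraries Nlrc5 turned to lower when each cell had equal weight and Tap1 within M1 macrophages alone, and H2-M3 turned to higher in the sorted libraries after thinning. Members of the H2 family share sequence and their counts are uncertain. NF-kB feedback genes had medians of 0.45 and 0.55 with 6 of 16 higher and 1 lower, led by Zfp36 (1.26, 1.85), Birc3 (1.48, 1.06), Tnfaip3 (1.08, 0.81) and Bcl3 (0.95, 0.79), with Sod2 lower (-0.63, -0.59). Chemokine receptors had 0.41 and 0.79 with 4 of 9 higher. Ccr2 (1.53, 2.44) and Cxcr4 (1.24, 1.60) were among them, and Ackr3 had -1.41 and -0.08.

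Hypoxia and glycolysis genes were lower: their median was -1.26 (-1.53 to -0.80) and -1.48 (-1.68 to -1.34), below every random list in both preparations, and 18 of 24 were lower and 0 higher. Hilpda, a lipid droplet protein induced by hypoxia, had -1.85 and -1.68, the glucose transporter Slc2a1 -1.53 and -2.44, Aldoa -1.73 and -1.64 and Tpi1 -1.54 and -1.53. Lipid-associated and lysosomal macrophage genes had medians of -0.74 (-1.29 to -0.32) and -0.50 (-0.74 to 0.01), with 8 of 20 lower and 1 higher. Trem2, a lipid receptor (-1.86, -1.22), Spp1, osteopontin (-1.78, -1.23), and Plin2 (-1.29, -1.01) were lower. Apoe was at 11007 CPM in WT and 4099 in KO sorted cells (-1.75; tumor -0.92, but 0.29 within M2 macrophages of the tumor libraries). Ctsk, a lysosomal protease, was higher (2.40, 0.71), though lower within M2 macrophages of the tumor libraries. Cell cycle genes had -0.66 (-0.998 to -0.15) and -0.24 (-0.48 to 0.01), with 3 of 22 lower and 0 higher. Cdk1 had -0.998 and -1.29, Ccnb1 -0.64 and -0.68, Tubb5 -0.68 and -0.63, Mcm3 -0.79 and -0.55 and Pcna, against them, 0.14 and 0.13. By total UMIs the cell cycle median of the tumor libraries was 0.08, and Mcm3 there turned to 0.19 when each cell had equal weight.

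Among the other lists, extracellular matrix remodelling genes had medians of 0.86 and 0.31 with 5 of 16 higher and 1 lower, led by Mmp9 (2.26, 4.90) and Tgfbi (0.91, 1.69), with Mmp19 at 0.73 and 0.94 and Thbs1 at -1.01 and -1.16. Mmp19 was lower within sorted M2 macrophages, and Thbs1 was higher (2.83) within M1 macrophages of the tumor libraries. Complement genes went both ways, with medians of -0.04 and 0.17, 5 of 13 higher and 2 lower: C3 (2.89, 4.27), C4b (2.17, 2.42), Itgax (2.04, 2.14) and Cfb (1.52, 2.19) were higher and C1qb lower (-1.67, -0.77), the latter higher within M2 macrophages of the tumor libraries. Inflammatory cytokines had -0.10 and 0.30 with 3 of 13 higher and 0 lower: Cd40 (0.86, 1.18), Il6 (1.70, 0.86) and Osm (0.80, 1.94) were higher, Il1b had 0.03 and 2.20 and Ptgs2 -0.41 and -2.01. Il6 was lower within sorted M2 macrophages, and Ptgs2 was higher within M1 macrophages of the tumor libraries. Dissociation and early stress genes, which can respond to tissue digestion, had 0.16 and 0.22 with 5 of 22 higher and 1 lower, from Nr4a1 (2.05, 1.28), Hspa1b (1.27, 1.53) and Dusp1 (0.87, 1.14) to Hspb1 (-2.55, -4.31). Checkpoint ligands had 0.19 and 0.35 with 1 of 11 higher, Pdcd1lg2, while Sirpa had 0.38 and 0.57 and Cd86 -0.86 and -0.25. The CD200 receptor family had 0.44 and 0.22 with 2 of 6 higher and 1 lower: Cd200r4, a neighbouring activating receptor gene, had 1.40 and 1.31 and the adaptor Dok1 -0.90 and -0.23.

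Some lists of RNA from other cell types differed too. Erythrocyte and platelet RNA had medians of -7.67 and -3.31 with 5 of 5 lower, in step with the hemoglobin RNA of the whole libraries. Fibroblast RNA had 1.04 in the sorted and -1.63 in the tumor libraries with 1 of 8 higher and 2 lower, from Fn1 (2.74, 0.64) to Col1a2 (-3.85, -7.18) and Lum (-1.49, -3.78). Regulatory T cell genes had 1.97 and -0.95 with 1 of 3 higher (Ikzf2, 2.498, 1.18) and 1 lower (Capg, -1.90, -0.95). Naive and memory T cell genes had 0.54 and 0.53 with 3 of 9 higher and 1 lower, such as Slamf6 (1.48, 1.38) and Igfbp4 (-0.85, -0.99). Exhaustion genes had 0.41 and -0.01 with 0 of 6 higher or lower in both, among them Nr4a2 (2.15, 0.30), Havcr2 (0.00, 0.13) and Entpd1 (-0.16, -0.15). Cytotoxic genes had 0.27 and 0.41, also with 0 of 6, and Zeb2 at 0.78 and 0.50. Neuroblastoma identity genes had 1.13 and -0.12 with 1 of 4 higher, Hand2 (1.66, 0.64), beside Cd276 (0.32, 0.59). T helper cytokines, with 7 members in the sorted libraries alone, had a median of 0.69, with Il17a at 5.57 from 5 UMIs in WT and 78 in KO, Areg at 1.54 (and -1.09 in the tumor libraries) and Ifng at -0.89. Hand2 and Capg turned within M2 macrophages and Entpd1 within M1 macrophages, and Ifng turned when each cell had equal weight.

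Across the 7455 genes, the log2 ratios of monocytes and macrophages in the sorted and tumor libraries had a Pearson r of 0.555 and a Spearman rho of 0.554. Genes are not independent replicates, so no p-value is given. In B cells r was 0.642 and rho 0.674 over 1319 genes. Taken alone, M1 macrophages had an r of 0.649 and M2 macrophages of 0.313.

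**Figure D3:**
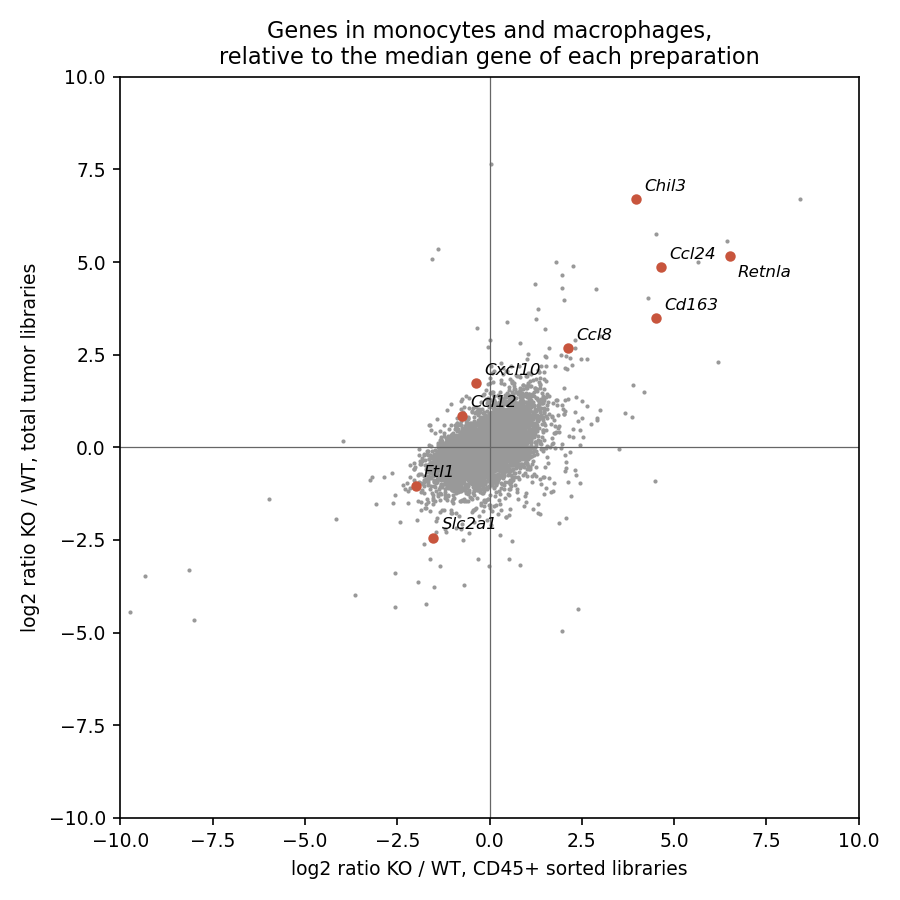
Log2 ratio KO over WT of 7455 genes in monocytes and macrophages, CD45+ sorted libraries on the x axis and total tumor libraries on the y axis, each relative to its median gene, 1 point per gene. Ccl24, Retnla, Chil3 and Cd163 lie far above 0 on both axes, and Cxcl10 and Ccl12 lie on opposite sides of 0.

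Neutrophils, dendritic cells, T cells, NK cells and regulatory T cells had fewer than 50 cells in at least 1 tumor library, so their genes were compared in the sorted libraries alone, apart from the ranking by size, and have no count over both preparations. Hypoxia and glycolysis genes were lower in KO in the first 4 of these, while in regulatory T cells the median was 0.00 (-0.33 to 0.41) with 4 of 23 higher and 5 lower. KO neutrophils had less RNA of chemokines and glycolysis genes: of 13 chemokines 11 were at least 1.5-fold lower and 1 higher, with a median of -2.27 (-3.72 to -0.63). Cxcl3 was at 13134 CPM in WT and 1427 in KO (-3.60), and Ccl5 (-4.44), Cxcl1 (-4.05) and Cxcl10 (-3.72) were lower, while Ccl9 was at 162 and 1194 CPM (2.49). Hypoxia genes had -1.76 with 22 of 24 lower and 0 higher, such as Hilpda (-3.03), Gapdh (-2.83) and Mif (-2.73), with Ndrg1 at 0.37 (-0.46 to 1.12). Plin2 (-3.01) and Upp1 (-3.34) were lower, and Fosb (3.65), Ier2 (1.961), Tnfaip2 (1.94) and Cyp11a1, a steroid synthesis enzyme (6.37), were higher. Genes of basophils and mast cells were higher in this class, Cd200r3 with 11.0 and 351 CPM (4.602), Gata2 (5.76) and Ms4a2 (3.62), and Il4 had 0 UMIs in WT and 16 in KO. Cells with at least 2 basophil or mast cell markers were 3 of 432 WT and 17 of 87 KO neutrophils. The gene values of this class, those of Ccl9 and Cyp11a1 among them, were not recomputed without these cells.

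In KO dendritic cells Ccl24 was at 29.0 CPM in WT and 446 in KO (3.66), Ccl17 at 79.8 and 279 CPM (1.52), Ccl22 at 243 and 762 CPM (1.37) and Ccl8 had 1.71. Ccl1 had 0 UMIs in WT and 216 in KO (at least 5.49). Ccl22 and Ccl17 are among the leading genes of the migratory class, 1 of the dendritic classes pooled here. Over 24 chemokines 7 were higher and 10 lower, with a median of 0.03 at percentile 83.5, and Pf4 had -3.83. Interferon gamma targets had 0.63 (0.26 to 0.86) with 9 of 17 higher and 1 lower, led by Iigp1, Gbp6 and Irgm2, with Psmb8 at -1.28. Hypoxia genes had -0.97 with 18 of 24 lower and 0 higher, from Bnip3 (-2.06), Slc2a1 and Aldoa to Pfkp (0.40). Genes of T cells were also higher in this class, regulatory T cell genes with 1.90 (-0.24 to 2.71; 6 of 11 higher, 1 lower) and T helper cytokines with 2.13 (-0.06 to 3.71; 5 of 6 higher, 0 lower), and lipid-associated macrophage genes were lower, with -1.01 (-1.32 to -0.68) and 16 of 20 lower. MHC class II genes had -0.42 with 2 of 12 lower, H2-Eb1 (-0.78) and Cd74 (-0.68), and Ciita had 0.26. Under the ranking that also requires the tumor libraries, the largest ratios were those of the lectin Cd209e (at least 6.74), Mucl1 (5.84), Ccdc80 (4.85) and Gm42031 (4.20), and the lowest those of Trem2 (-3.52), Apoe (-3.20), Ankrd37 (-3.01) and C5ar1 (-2.82), the last the receptor of complement C5a.

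In T cells of KO tumors regulatory T cell genes had 1.39 (-0.77 to 1.957) with 8 of 11 higher and 2 lower: Il2ra (2.51), Ctla4 (1.957) and Il10 (1.95) were higher and Capg lower (-1.25). The same list was higher in sorted monocytes and macrophages (1.97), dendritic cells (1.90) and NK cells (0.90, -1.95 to 2.26; 5 of 8 higher, 2 lower), though not in B cells (-0.17), in a KO library with a larger regulatory T cell class, so cells or RNA of that class are not excluded as its source. Exhaustion genes had 0.62 (0.31 to 1.53) with 7 of 12 higher and 1 lower, from Cd244a (2.32) and Nr4a2 (1.53) to Cd160 (-1.58). Type I interferon genes had -0.72 (-1.23 to -0.09; -0.14 by total UMIs) with 13 of 24 lower and 3 higher: Ifit3, which has a near-identical copy, had -3.13, Isg15 -2.86 and Rsad2 1.00 (-0.11 to 2.19). Cytotoxic genes had -0.29 (-0.98 to 0.57) with 7 of 22 lower and 5 higher, such as Gzmd (-2.26), Ccl5 (-1.63) and Gzma (2.16), and hypoxia genes -0.72 (-0.15 by total UMIs) with 10 of 20 lower and 1 higher, such as Gapdh (-1.40) and Ldha (-1.26). RNA of other cell types was lower in this class too, lipid-associated macrophage genes with -1.07 (-2.00 to -0.37; 11 of 18 lower, 0 higher), complement genes with -1.15 (-2.81 to 2.66) and erythrocyte and platelet RNA with -3.12 (3 of 3 lower). Under that ranking, Cxcr4 (2.18), Maf (1.93), Nr4a3 (2.59) and Sod1 (1.94) were highest and Socs3 (-3.40), Cdkn2d (-2.39), Socs1 (-2.33), Dapl1 (-2.22) and Mrpl58 (-2.22) lowest.

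KO NK cells had less RNA of Gzmc, Gzmd and Gzmf: Gzmc was at 9880 CPM in WT and 2627 in KO (-2.27), Gzmd at 5601 and 1117 CPM (-2.68) and Gzmf at 5097 and 616 CPM (-3.41). These granzymes are among the genes that define the class, and over 21 cytotoxic genes 8 were lower and 3 higher, with a median of -0.41 (-0.72 to 0.20), at percentile 40.6 of the random lists, and Tbx21 at 1.55. Macrophage RNA was lower in this class, lipid-associated genes with -2.31 (-3.79 to -1.35; 18 of 19 lower), complement genes with -4.24 (-5.05 to 1.07; 6 of 8 lower, 1 higher) and alternative activation genes with -2.13 (-3.31 to 0.61; 11 of 17 lower, 5 higher). Cell cycle genes had -1.02 (-1.65 to -0.27) with 15 of 22 lower and 1 higher. Interferon gamma targets had 0.73 (0.26 to 0.96) with 10 of 17 higher and 2 lower, such as Irgm2 (3.89, from 2 UMIs in WT), Iigp1 (3.64, from 3 UMIs in WT) and Psmb8 (-1.65). Hypoxia genes had -1.08 with 17 of 23 lower and 1 higher, such as Egln3 (-3.00) and Gapdh (-1.82), with Vegfa at 1.30. Under the ranking that also requires the tumor libraries, Gm42031 (4.59), Dgat1 (2.39), Satb1 (2.29), Fosl2 (2.25) and Nr4a2 (2.22) were highest and Birc5 (-2.79), Ssr4 (-2.13), Emp3 (-1.99), Hsd17b10 (-1.95) and Cks1b (-1.92) lowest. In the regulatory T cell class, 94 WT and 396 KO cells, regulatory T cell genes had 1.56 (0.34 to 2.67) with 9 of 11 higher and 1 lower: Tnfrsf9 (2.88), Il10 (2.67), Il2ra (138 and 787 CPM, 2.08), Ctla4 (1.64) and Foxp3 (91.4 and 364 CPM, 1.56) were higher and Capg lower (-1.07). Il1rl1, the receptor of interleukin 33, was at 38.9 and 408 CPM (2.96), and Arl5a (2.04), Gata3 (1.71) and Klrg1 (1.68) were higher. T helper cytokines had 0.81 (-0.96 to 2.51) with 7 of 13 higher and 4 lower, such as Il13 (3.65), Il5 (at least 2.51) and Csf2 (-2.19). B cell RNA was lower in these cells, Igkc with -3.46 and Cd79a with -2.53, as were Tmem176b (-3.18), Socs3 (-2.61) and Trdc (-2.51). Areg had 0.32, which turned to lower without doublets, with equal weight per cell and after thinning, and Rora had 1.10.

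B cells, with 972 WT and 943 KO cells in the sorted and 58 and 327 in the tumor libraries, had 126 genes at least 2-fold higher and 6 lower in KO in both preparations by total UMIs among 1319 (95.5% higher), and 61 and 26 relative to the median gene (70.1% higher). In each case 1 gene was in opposite directions. Cxcr4, the receptor of Cxcl12 (2.24 sorted, 1.88 tumor), the transcription factor Irf4 (2.001, 2.04), Elmsan1 (2.04, 1.81), Fnip1 (2.05; 2.34, -0.26 to 7.70, tumor) and Gm49980 (2.72, at least 0.81) were highest. Ubb (-3.05, -1.27), Jun (-2.66, -1.78), Hist1h1d (-2.78, -2.42), Lgals1 (-2.54; -1.17, -2.43 to 0.23, tumor) and Iglc1 (-2.44, -1.68) were lowest. Hypoxia genes had -0.83 (-1.27 to -0.22) and -0.27 (-1.14 to 0.83) with 4 of 11 lower and 0 higher, such as Eno1, Tpi1 (-1.47, -1.14) and Aldoa. In the sorted libraries RNA of other cell types and stress genes were lower as well, lipid-associated macrophage genes with -1.13 (-2.36 to -0.70; 14 of 18 lower, 2 higher), complement genes with -2.18 (4 of 5 lower), erythrocyte and platelet RNA with -3.10 (5 of 5 lower) and dissociation and early stress genes, Jun among them, with -0.89 (-1.28 to -0.12; 13 of 22 lower, 1 higher), against 0.01 for lipid-associated, 2.61 for erythrocyte and platelet and -0.25 for stress genes in the tumor libraries. MHC class I genes had -0.50 (-0.87 to -0.03) and -0.09 (-0.46 to 0.04) with 2 of 17 lower and 0 higher, such as Psme2 (-0.90, -1.14), H2-T22 (-0.61, -0.96) and, against them, Tapbp (0.59, 0.58). The interval spanned 0 for H2-T22 and Tapbp in the tumor libraries.

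Cells named neuroblastoma (205 WT and 171 KO sorted, 1665 and 1283 tumor) and fibroblasts (164 and 78, 2461 and 2493) shared a set of genes near 0 in KO alone. In the tumor libraries Hoxd11, a homeobox gene, was at 89.6 CPM in WT and had 0 UMIs in KO neuroblastoma cells, and Acot1, which has near-identical copies (-9.49), Col1a2, a chain of type I collagen (366 and 0.623 CPM, -9.39), Nsg1 (-8.50) and Fbxl7 (-8.22) were lowest. Among fibroblasts Catsperz was at 57.6 CPM in WT with 0 UMIs in KO, and Hoxd11 (-9.75), Acot1 (-7.97), Peg3 (-7.88) and Col25a1 (-7.88) were lowest. Col8a1, a collagen of basement membranes, was higher in both, with 3.02 and 2.35, and so was Prph, an intermediate filament protein of peripheral neurons, with 2.25 and 2.19. Neuroblastoma cells also had more Efemp1 (2.33), C130073E24Rik (2.16) and Cpe (2.06), and fibroblasts more Igfbp6 (2.27), Fign (2.02) and Atf3 (1.95), the last turning to lower in the sorted libraries with equal weight per cell. Of 9918 genes in neuroblastoma cells 308 were higher and 217 lower in both preparations by total UMIs (58.7% higher, 62 opposite), and 176 and 296 relative to the median gene (37.3% higher, 60 opposite). Of 9027 genes in fibroblasts 630 were higher and 202 lower (75.7% higher, 45 opposite), and 285 and 339 relative to the median gene (45.7% higher, 47 opposite). After thinning these counts were 28 and 14 in neuroblastoma cells and 23 and 18 in fibroblasts. Thinning removes most UMIs of these deep cells, so fewer genes can be called, and the fall does not show that depth lay behind the differences.

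In cells named neuroblastoma interferon gamma targets had medians of 1.15 (0.68 to 1.67) and 1.05 (-0.09 to 2.04) with 10 of 16 higher and 0 lower, led by Iigp1, Gbp4, Gbp2 and Gbp6, with Psmb8 against them (-0.47, -1.64). The leading genes of this class are cell cycle genes. In the sorted libraries it held Cd200r1 at 25.3 CPM in WT and Y-linked RNA, which marks the male hosts, at 95.1 CPM in WT and 145 in KO, against 148 and 201 in monocytes and macrophages and 0.139 and 0.503 in the same class of the tumor libraries. The sorted cells of this class are thus host cells to a large part, the tumor libraries stand for the graft, and counts over both preparations compare different cells. Identity genes of neuroblastoma had 0.92 (-0.53 to 3.08) and 0.45 (0.27 to 3.19) with 2 of 9 higher and 1 lower, Gap43, Gata3 and Ncam1 leading and Ddc lower (-1.52, -1.08). Mycn had 0.90 (-0.19 to 1.997) and 0.27 (-0.02 to 0.57). Hypoxia genes had -0.73 (-1.26 to -0.36) and -0.70 (-0.85 to -0.61) with 13 of 24 lower and 0 higher, such as Adm (-1.75, -1.73), Pfkl, Tpi1 and Aldoa, with Pdk1 at 0.55 and 0.89. In cells named fibroblasts Y-linked RNA was at 13.6 CPM in WT and 4.79 in KO of the sorted and at 0.332 and 1.12 of the tumor libraries. Most of these cells may thus come from the graft, and counts over both preparations may compare different cells here too. In fibroblasts type I interferon genes had 0.83 (0.15 to 1.43) and 1.18 (0.81 to 1.45) with 11 of 22 higher and 0 lower, led by Ifi205, Oasl2, Ifih1 and Isg15, with Isg20 at -0.89 and -0.10. Interferon gamma targets had 0.24 (-1.66 to 1.63) and 1.34 (0.45 to 2.42) with 6 of 13 higher and 2 lower, such as Gbp2 (2.43, 3.54), Irgm2 (2.39, 1.86) and Psmb8 (-3.29, -1.52). Hypoxia genes had -1.03 (-1.24 to -0.59) and -1.06 (-1.23 to -0.67) with 18 of 24 lower and 1 higher, such as Adm (-1.31, -1.23), Hilpda (-2.26, -1.23), Aldoa and Tpi1, with Pdk1 at 0.93 and 0.71. Cxcl10 was higher in fibroblasts (1.54, 1.94), and Cxcl1 had 0.58 and 1.08, the former turning to lower with equal weight per cell. The chemokines as a list went opposite ways in fibroblasts, with -2.08 (-3.86 to 0.32; 14 of 21 lower, 3 higher) in the sorted and 1.68 (0.42 to 2.79; 18 of 26 higher, 3 lower) in the tumor libraries, and 2 of 20 were higher and 1 lower in both. So did lists of leukocyte RNA, MHC class II genes with -1.37 (-1.99 to -0.70) and 1.94 (1.02 to 2.74) and cytotoxic genes with -3.03 (-6.77 to -1.28) and 2.87 (-2.57 to 5.80).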

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

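The tests of the opposite chemokines were chosen before their outcome was seen, apart from that with limits of the B cell level, and the comparison of the share was not tested further. In monocytes and macrophages 7 chemokines had log2 ratios KO over WT of opposite sign in the CD45+ sorted and the total tumor libraries, with both counting intervals apart from 0, but only Ccl12 and Ccl5 by at least 1.5-fold in each. Ccl12 had -0.75 in the sorted and 0.85 in the tumor libraries, Ccl3 -1.14 and 0.31, Ccl4 -0.55 and 1.06, Ccl5 -1.39 and 5.36, Ccl7 -0.34 and 0.99, Cxcl10 -0.36 and 1.73 and Cxcl1 0.45 and -0.59. The difference between the preparations was not tested, as there is 1 library for each. The share of monocytes and macrophages among all cells also differed in direction, with KO minus WT at -12.5 percentage points in the sorted and 2.44 in the tumor libraries, a difference that was not tested either. The denominators differ, because the tumor libraries hold graft cells: with leukocytes alone as denominator KO minus WT was -16.4 points in the sorted and -29.5 points in the tumor libraries.

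Subtracting the level in B cells of the same library, after which all 7 kept opposite directions, cannot tell whether free RNA accounts for them, because B cells of the WT tumor library had 0 UMIs for 6 of the 7. Free RNA within the counting limits of the level in B cells does not account for them: with the limits least favourable to each direction subtracted, all 7 kept opposite directions, Ccl3 of the tumor libraries only just, at 0.055. A different mixture of the M1 and M2 macrophages named by the authors does not account for most of them, since 6 of the 7 had opposite directions within M2 macrophages alone (all but Cxcl1) and 5 within M1 macrophages alone (all but Ccl3 and Cxcl10). Depth per cell does not account for most of them among cells of at least 2000 UMIs, as 6 of the 7 (all but Cxcl1) kept opposite directions after thinning. Thinning leaves out shallower cells, 80 of 1577 WT sorted, 104 of 761 KO sorted, 48 of 191 WT tumor and 134 of 371 KO tumor monocytes and macrophages, so it also changes which cells are compared. For Cxcl1 depth, the cells left out and mixture stay open: its sorted value was -0.21 after thinning and -0.49 within M2 macrophages. A difference between the animals or digestions behind the libraries stays open, as does a real dependence on the preparation, and no biological explanation was tested.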

How the results depend on the processing

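Counts relative to the median gene, gene and list values by total UMIs, and the removal of cells with basophil markers from neutrophils were chosen after the data were seen, the other alternatives before. No paired analysis was possible because the cells of the samples 1a to 1d of a group cannot be told apart. For the same reason a DESeq2 or edgeR test, a replicate block and leaving out samples did not apply. The authors' annotation holds no monocyte class, so M1 and M2 macrophages took the place of macrophages and monocytes apart. Thinning gave no count of genes in B cells, as few tumor B cells reach 2000 UMIs. Values of genes are log2 ratios KO over WT, and values of shares are KO minus WT in percentage points. The cause of the differences listed was not tested, unless said.

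Of 54 shares recomputed, 27 stayed within their interval, 25 moved without a change of direction and 2 turned. With the stricter cell filter the sorted shares were -14.5 for monocytes and macrophages, 4.98 for dendritic cells and 8.62 for regulatory T cells, and the tumor shares 3.31 for monocytes and macrophages, 4.29 for T cells, 2.48 for regulatory T cells, -14.4 for fibroblasts and 18.5 for leukocytes. Without doublets they were -15.7 for sorted monocytes and macrophages, 6.77 for sorted B cells and -9.62 for neuroblastoma cells of the tumor libraries. With classes rebuilt from markers they were -15.3 for monocytes and macrophages, 5.03 for dendritic cells, 6.25 for regulatory T cells and 4.53 for NK cells in the sorted libraries, and 1.09 for regulatory T cells, 5.09 for B cells, -50.5 for fibroblasts and 17.8 for leukocytes in the tumor libraries, while neuroblastoma cells turned to 16.1. The rebuilt class was that of the authors for 73.3% of WT sorted, 68.4% of KO sorted, 43.9% of WT tumor and 37.4% of KO tumor cells. With leukocytes alone as denominator the sorted shares were -16.4 for monocytes and macrophages, -8.00 for neutrophils and 9.17 for regulatory T cells, and the tumor shares 10.8 for T cells, 7.51 for regulatory T cells and 8.37 for B cells, while monocytes and macrophages turned to -29.5, because graft cells leave the denominator. Without cells with basophil markers the neutrophil share stayed within its interval.

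Of 106 counts of genes recomputed, 50 stayed within 1.5 times the reported count and 56 did not. Thinning also cuts the UMIs of each class, so fewer genes can be called after it. In monocytes and macrophages (418 higher, 38 lower) the number higher was 129 with TMM, 139 with median of ratios, 159 relative to the median gene, 788 with no low-count filter, 239 with at least 100 UMIs, 151 after thinning, 1339 at 1.5-fold, 240 within M1 and 228 within M2 macrophages alone. The number lower was 121 with TMM, 111 with median of ratios, 101 relative to the median gene, 62 with no filter, 67 with equal weight per cell and 130 at 1.5-fold. In B cells (126 higher, 6 lower) it was 71 higher and 18 lower with TMM, 60 and 19 with median of ratios, 61 and 26 relative to the median gene, 46 higher with at least 100 UMIs, 83 higher with the cell filter, 20 lower with no filter and 36 lower at 1.5-fold. In fibroblasts (630 higher, 202 lower) it was 265 higher and 365 lower with TMM, 263 and 367 with median of ratios, 285 and 339 relative to the median gene, 1202 and 311 with no filter, 166 and 56 without doublets, 23 and 18 after thinning, 1968 and 416 at 1.5-fold, and 378 higher with at least 100 UMIs. In neuroblastoma cells (308 higher, 217 lower) it was 160 higher with TMM, 157 with median of ratios, 176 relative to the median gene, 686 with no filter and 194 with at least 100 UMIs, and 143 higher and 57 lower without doublets, 28 and 14 after thinning and 1202 and 440 at 1.5-fold. The excess of higher over lower genes thus depends on scaling, and in fibroblasts and neuroblastoma cells (310, 312 and 296 lower) it turns to more lower than higher with TMM, median of ratios and the median gene, as it does within M2 macrophages alone relative to the median gene (62 higher, 88 lower). Of the chemokines in monocytes and macrophages, 2 were higher in both preparations with equal weight per cell, 2 after thinning, and 1 was lower without doublets, 0 at 2-fold and 1 by total UMIs.

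Of 494 list medians, 473 stayed within their interval and 21 did not. By total UMIs, which adds the shift of the median gene, the medians were 0.10 for MHC class I in B cells of the tumor libraries and -0.69 for lipid-associated genes in sorted B cells, 1.09 for interferon gamma targets in NK cells, -0.15 for hypoxia, 1.960 for regulatory T cell genes and 0.72 for interferon gamma targets in T cells, 0.44 for hypoxia and 0.66 for interferon gamma targets in regulatory T cells, -0.69 for hypoxia and 0.91 for interferon gamma targets in dendritic cells, 1.47 for type I interferon genes in fibroblasts of the tumor libraries, -0.50 for hypoxia in neuroblastoma cells of the tumor libraries and, in monocytes and macrophages, 0.57 for MHC class I (sorted), 0.075 for cell cycle (tumor) and -1.17 for hypoxia (tumor). Hypoxia in sorted monocytes and macrophages had -1.58 with equal weight per cell and -1.55 after thinning, and in neutrophils -2.30 with TMM. Interferon gamma targets in monocytes and macrophages of the tumor libraries had 0.85 with equal weight per cell, 0.72 within M1 and 2.33 within M2 macrophages.

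Of 3663 values of named genes, 2378 stayed within their counting interval, 1245 moved in the same direction or without a called direction, and 40 turned. In monocytes and macrophages these were, within M1 macrophages alone, Cxcl10 0.16 and Entpd1 0.15 (sorted) and Ccl2 0.14, Ccl3 -0.031, H2-DMb1 -0.25, Tap1 -0.21, Thbs1 2.83, Mcm3 0.011 and Ptgs2 1.02 (tumor). Within M2 macrophages alone they were Ccl6 -0.68, Ccl9 -0.45, Cxcl1 -0.49, Mmp19 -0.19, Il6 -0.27 and Cd200 -0.80 (sorted) and Folr2 0.060, Apoe 0.29, Ctsk -0.24, C1qb 1.12, Hand2 -0.57 and Capg 0.054 (tumor). With equal weight per cell they were Cxcl1 -0.34, Cd200 -0.11 and Ifng 1.35 (sorted) and Nlrc5 -0.41 and Mcm3 0.19 (tumor), in sorted fibroblasts Atf3 -0.16 and Cxcl1 -0.20, and in regulatory T cells Areg -0.23. After thinning they were Cxcl1 -0.21, H2-M3 0.21 and Cd200 -0.62 (sorted), and Areg -0.13 in regulatory T cells. Without doublets they were Xcl1 0.045 and Cd200 -0.24 (sorted) and Slpi 1.22 (tumor), and Areg -0.35 in regulatory T cells, and with the cell filter Slpi 2.66 (tumor). By total UMIs they were H2-M3 0.0035 and Entpd1 0.16 (sorted). Ccl24, Ccl8, Retnla and Chil3 kept their direction under each alternative run.

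With at least 200 UMIs the correlation of the preparations in monocytes and macrophages was 0.635 (Pearson) and 0.581 (Spearman), and in B cells 0.720 (Pearson). Thinning limits detection by its own construction: the share of cells with a UMI was then, for Cd200r1, 11.1% in WT sorted and 9.09% in WT tumor monocytes and macrophages and 4.76% in WT sorted dendritic cells, and for Cd200 11.9% in WT and 20.95% in KO B cells and 10.6% in WT and 16.2% in KO dendritic cells of the sorted libraries.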

Other observations

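The tests on alternative activation were all chosen after the result was seen, as were those on classes of cells and on Y-linked RNA among the tests on the graft, while the test on chromosomes was chosen before. Across classes, hypoxia and glycolysis genes were lower in KO in monocytes and macrophages, neutrophils, dendritic cells, T cells, NK cells, sorted B cells, neuroblastoma cells and fibroblasts, with a median log2 ratio as low as -1.76 in sorted neutrophils. They were not in regulatory T cells (0.00, -0.33 to 0.41), and B cells of the tumor libraries had -0.27 (-1.14 to 0.83). These are targets of hypoxia-inducible factors and enzymes of glucose use, and monocytes, macrophages and graft cells of the tumor libraries shared the direction. By total UMIs the hypoxia median was -0.15 in T cells and 0.44 in regulatory T cells, so in these classes it depends on scaling. Lipid-associated macrophage genes were also lower in T cells, NK cells, dendritic cells and sorted B cells, as given above. Whether macrophage RNA carried into these classes lies behind their hypoxia values was not tested. Interferon gamma targets were higher in monocytes and macrophages, dendritic cells, NK cells, sorted cells named neuroblastoma and fibroblasts of the tumor libraries, with intervals that spanned 0 in neuroblastoma cells of the tumor libraries (-0.09 to 2.04) and sorted fibroblasts (-1.66 to 1.63), yet Psmb8, an immunoproteasome gene of the same list, was lower in the sorted libraries of these 5 classes. No such direction was seen in T cells (0.15, -0.82 to 0.57), sorted B cells (0.04, -0.63 to 0.57) or neutrophils (-0.02), and regulatory T cells had 0.23 with 5 of 17 higher and 5 lower. This depends on scaling, since by total UMIs T cells had 0.72 and regulatory T cells 0.66. Gm42031 (chromosome 8, 85125872 to 85132289, minus strand), a long noncoding RNA, was higher in monocytes and macrophages (4.52), dendritic cells (4.20) and NK cells (4.59).

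Retnla, Chil3, Chil4, Cd163 and other alternative activation genes were higher in KO monocytes and macrophages together with Ccl24 and Ccl8. A different mixture of the authors' macrophage classes does not account for most of this: of 13 genes at least 1.5-fold higher in both preparations, 9 were so within M1 macrophages alone and M2 macrophages alone in both preparations. Retnla and Mgl2 are also among the leading genes of the class named myeloid dendritic cells. Whether such cells lie within both macrophage classes was not tested, and this split cannot tell. Of the others, Arg1 turned to -0.69 and Il4ra had 0.10 within sorted M2 macrophages, and Mrc1 had 0.54 within M1 macrophages of the tumor libraries. Pdcd1lg2 had too few UMIs within M2 macrophages of the tumor libraries. Only 1 of the 13, Retnla (chromosome 16, 48842551 to 48844461, plus strand), lies within 20 Mb of Cd200r1, at 4.08 Mb. DNA of another strain around the targeted locus, acting on the genes it holds, thus does not account for the others, but for Retnla it stays open. Gene positions cannot tell whether such DNA acts on genes elsewhere, so that stays open for the whole set. Of 84 genes measured within 20 Mb of Cd200r1, 6 were at least 2-fold higher and 2 at least 2-fold lower in both preparations (9.52%), against 3.42% of 7371 other genes. The 84 genes include Cd200r1 itself, among the lower ones, and Retnla, among the higher ones. Part of the excess thus rests on the deleted gene and on a gene already named, and no interval was computed for it. Free RNA in B cells of the KO sorted library was far below the macrophage level, with Ccl24 at 7.60 CPM, Ccl8 at 42.9 CPM and Retnla at 34.0 CPM.

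Interleukin 4 and 13 induce Retnla, Chil3 and Chil4 in mouse macrophages, which is not claimed for every gene of the set. After thinning, which leaves out cells below 2000 UMIs, a UMI of Il4, Il5 or Il13 was found in 1 of 3812 WT sorted leukocytes (0.0262%) and in 36 of 2764 KO sorted leukocytes (1.30%), a share 49.6 times as high in KO (8.36 to 2015), a ratio that rests on 1 WT cell. Without thinning the shares were 0.365% and 1.91%, a ratio of 5.23 (2.95 to 9.87). The cells named hematopoietic stem cells, whose leading genes include the mast cell genes Cma1 and Mcpt4, are not among these leukocytes. Type 2 cytokine RNA in them was not counted. Without thinning 9 of the 15 WT and 12 of the 66 KO cells were monocytes and macrophages (0.571% and 1.58% of that class), where such a UMI can be free RNA, and after thinning 0 and 2. The share was 10.3% of KO neutrophils (4.84 to 18.7; WT 0%, 0 to 0.850) and 8.59% of the KO regulatory T cell class (6.02 to 11.8), where the WT interval overlaps (5.32%, 1.75 to 12.0). After thinning the regulatory T cell class had 1.22% in WT (0.0309 to 6.61) and 6.25% in KO (3.91 to 9.40), again with overlapping intervals. The larger size of that class adds to the number of such cells, and a higher share within it stays open. These classes also hold markers of basophils and of group 2 innate lymphoid cells. In the tumor libraries such a UMI was found in 0 of 321 WT leukocytes (0 to 1.14%) and 12 of 1237 KO leukocytes (0.970%, 0.502 to 1.69). After thinning these were 0 of 191 (0 to 1.91%) and 4 of 557 (0.718%, 0.196 to 1.83). The intervals overlap, so the tumor libraries cannot tell whether the share differs. A larger supply of type 2 cytokines is a candidate explanation of the genes they induce, such as Retnla, Chil3 and Chil4, and not of the whole set. With 1 library per genotype a difference between animals, such as a response present in the KO tumors alone for another reason, stays equally open. RNA levels do not show cytokine release.

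Neuroblastoma cells and fibroblasts of the tumor libraries had 12 and 13 genes at no less than 50 CPM in WT and near 0 in KO (log2 ratio beyond 5), 8 of them in both (Hoxd11, Crabp2, Nsg1, Col1a2, Peg3, Acot1, Fbxl7 and Cpne5), and 0 genes the other way. Cells moved from 1 of these classes to the other do not account for genes near 0 in both. Over all non-leukocyte cells the median size of the log2 ratio of these genes was 7.12. That value had to be large, because the genes were picked as near 0 in the classes that hold most non-leukocyte UMIs. It therefore cannot tell whether cells moved to a smaller class. Y-linked RNA was at 95.4 CPM in WT and 167 CPM in KO endothelial cells of the male hosts and at 0.332 and 1.12 CPM in fibroblasts, at most 0.673% of the endothelial level (0.349% in the other genotype), so most cells named fibroblasts may come from the graft. The median gene lay beyond 0.3 (log2) in both classes and within 0.15 in monocytes and macrophages for 4 chromosomes: chromosome 13 (-0.33 in neuroblastoma cells, -0.31 in fibroblasts), 14 (-0.45, -0.36), 15 (-0.42, -0.37) and 18 (0.38, 0.34). In monocytes and macrophages of the tumor libraries they had 0.02, -0.14 (-0.24 to -0.05), -0.05 and 0.14 (0.08 to 0.24), so 14 and 18 barely pass, with a shift in the same direction there, and 18 was shifted in sorted ones too (0.17, 0.10 to 0.26). Chromosomes 10 (-0.30, -0.28) and 1 (-0.25, -0.23) were also lower in both classes, but so were they in monocytes and macrophages of the tumor libraries (-0.26, -0.16), though not in sorted ones (0.02, -0.07 to 0.07, and 0.11, 0.03 to 0.18). Whether graft RNA among the cells of the tumor libraries lies behind the former was not tested. A graft of another clone or passage in the KO mice, with other chromosome copies and silenced genes, is a candidate explanation. If so, differences of the graft and of the host genotype are mixed in every comparison, since 1 graft library stands for each genotype.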
